A study of Mus musculus with 19 samples.

How the data were processed

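Total RNA from primary mouse myocytes was labelled with biotin and hybridised to Illumina mouse BeadChips, per the labels' protocols. The cultures received ethanol vehicle (7 arrays), 1.5 µg/ml sanguinarine (4 arrays) or 25 µg/ml sanguinarine (8 arrays) for 60 minutes. Groups and replicate numbers were taken from the sample titles, and the BeadChip of each array from the chip part of its label. BeadChip 1 held 2 vehicle, 2 low dose and 2 high dose arrays. BeadChip 2 held 2 vehicle, 2 low dose and 1 high dose array, BeadChip 3 held 2 high dose arrays, and BeadChip 4 held 3 vehicle and 3 high dose arrays. Which BeadChip belongs to which experiment is not given in the sources used here.

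The authors deposited the scanner signal intensity of 45281 probes on each array and a detection p-value beside each signal. GenomeStudio 1.0 is named in the submitters' processing notes. The deposited intensity values are linear and not normalized between arrays: their means per array ran from 232 to 604. A second deposited table holds the authors' processed intensity of the same arrays. Each of its columns has the same order of probes as the scanner column of that array (Spearman's rho 1). Its medians lie between 61.9 and 62.0 and every column reaches the same highest value of 47252, so it is linear and quantile-normalized, with no centring of genes. No ratio is involved, so no direction is in doubt.

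Probes were named by the gene symbol in the deposited probe description, or else by the deposited probe name, and symbols were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. Of 45281 probes, 24202 matched a current symbol, 10819 an older one, 157 were ambiguous and 10103 kept the deposited name. A transcript description was present for 17962 probes and absent for 27319. No coordinates are given because the genome build of the array is not given in the sources used here.

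Signals were background-corrected with normexp from the detection p-values, with an offset of 16, quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Fold changes of dim genes are understated on this scale. Probes with a detection p under 0.05 on at least 4 arrays were kept (21302 probes), and each gene was represented by its probe with the highest mean, which left 14525 genes. A linear model with the group and the BeadChip as terms was fitted to all 19 arrays together with limma's lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method. A gene counts as changed at an adjusted p under 0.05, and the number that also reached an absolute log2 fold change of 1 is given beside it. Errors of fold changes are standard errors of this model (n = 7, 4 and 8). High dose arrays 4 and 5 were the only arrays of BeadChip 3, so its term absorbs their level. They add to the estimate of spread but not to any difference between groups, and leaving out either does not test the fold changes.

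Gene lists for 22 responses and 8 cell types were fixed before the data were examined, as were the tests and most alternatives. They were tested with camera at a preset correlation of 0.01 where at least 5 members were measured (28 of 30 lists), with camera at an estimated correlation and with fry (statmod 1.5.0) as alternatives. None of the list calls of the 3 comparisons held with an estimated correlation. Fry asks whether the members of a list move on balance one way and does not compare them with other genes.

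The rule for named genes was also fixed before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls (5 and 5 between the doses) that passed the threshold and had the same sign on every BeadChip holding both groups, leaving unnamed those with only clone or predicted-gene names. It added from each list the 2 largest rises and the 2 largest falls past the threshold, and 15 stress, muscle and reference genes whatever their values. Apart from 8 results that are not reported here, for a reason unrelated to their values, it gave 246 named results over the 3 comparisons, counting a gene once per comparison, 215 of them past the threshold, and 23 results with clone or predicted-gene names. Which of the 246 the report describes and which are only listed among the other observations was decided after their values and their values under the alternatives had been seen. The counts of alternatives start from all 246. A gene without a probe, or a comparison without both groups, under an alternative was not tested there and is not counted as lost. A gene not above background on any array of a group was given as a bound, which applied to Synpo2 at the high dose. Different probes of a gene can disagree: at the high dose 537 genes had probes called in opposite directions, 15.2% of the 3522 genes with several probes of which at least 1 was called.

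Principal components were computed on the normalized log2 values of the genes tested. Mean signals were compared by exact permutation within BeadChips. The correlation of the 2 doses was set against 100 simulations that rotated the residuals of the model at random, and was repeated with the vehicle arrays divided between the doses.

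The model was tested on simulated data with the means, BeadChip effects and residual spread of these arrays, 14525 genes and 50 genes changed at each of 4 sizes. For the high dose against vehicle it recovered 52% of changes of 0.5, 90% of changes of 1 and 100% of changes of 2 and 3 on the log2 scale, and 6.56% of its calls were false. For the low dose against vehicle the shares were 42%, 82%, 100% and 100%, with 7.95% false calls. For the high against the low dose they were 34%, 80%, 100% and 100%, with 8.19% false calls. The simulated noise was independent between genes, and few genes were changed, after normalization. These shares therefore need not hold for the real arrays.

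The alternatives were other normalizations (cyclic loess, median scaling), other background corrections, the authors' processed intensity on the log2 scale, other filters on dim probes, every probe tested on its own, other treatments of the BeadChip, subsets of the BeadChips, a replicate block, an intensity trend, array weights, a stricter threshold and leaving out each array in turn. After seeing the data, 3 were added: no scaling between arrays, leaving out BeadChip 3 together with high dose array 3, and only probes with a transcript description.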

Results

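Gene expression was measured in primary mouse myocytes, muscle cells taken from the animal and grown in culture, after 60 minutes of exposure to sanguinarine or to its ethanol vehicle. Sanguinarine is a plant alkaloid of the benzophenanthridine class. Total RNA was hybridised to 19 Illumina mouse BeadChip arrays. The vehicle group held 7 arrays, the low dose group (1.5 µg/ml) 4 arrays and the high dose group (25 µg/ml) 8 arrays. The submitters describe these as biological replicates from 3 experiments, without naming the experiment of each. Where arrays came from the same experiment, the spread between them may be smaller than between independent cultures. The arrays lay on 4 BeadChips, numbered 1 to 4 here. BeadChips 1 and 2 held all 3 groups, BeadChip 3 held high dose arrays only, and BeadChip 4 held vehicle and high dose arrays.

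Between 17389 and 19680 of 45281 probes per array were detected above the negative controls at a detection p under 0.05. The mean scanner signal was 474 ± 71.9 (SD, n = 7) for vehicle, 462 ± 142 (SD, n = 4) for the low dose and 343 ± 91.8 (SD, n = 8) for the high dose. Within BeadChips, the high dose signal was 0.741 times the vehicle signal (exact two-sided permutation test within BeadChips, 360 arrangements, p = 0.00556, adjusted p = 0.0167 over 3 comparisons). The ratio was 0.621 on BeadChip 1, 0.762 on BeadChip 2 and 0.862 on BeadChip 4. The low dose signal was 0.984 times the vehicle signal (exact permutation p = 0.889, adjusted p = 0.889). The high dose signal was 0.699 times the low dose signal (exact permutation p = 0.0556, the smallest p that 18 arrangements allow in this two-sided test; adjusted p = 0.0833). The number of arrays limits the precision of all values that follow.

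Of the cell type markers on the array, the filter on dim probes kept 17 of 17 for cardiomyocytes and 20 of 27 for the sarcomere and skeletal muscle. It kept 8 of 18 for myogenic regulators and myoblasts and 10 of 10 for smooth muscle. For fibroblasts it kept 11 of 16, for endothelial cells 6 of 12, for leukocytes 4 of 13 and for adipocytes 3 of 10. The median log2 level of the kept markers was 13.4 for cardiomyocytes, 9.45 for the sarcomere list and 6.64 for myogenic regulators. Cardiomyocyte markers were thus all kept and were the brightest of these 3 lists, while most myogenic regulators were not kept. Myog was above background on 5 of 7 vehicle, 1 of 4 low dose and 4 of 8 high dose arrays. These levels argue for heart muscle rather than skeletal muscle as the main source of the cultures. The sarcomere list is named for skeletal muscle, but its name does not settle the source.

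The first principal component held 42.5% of the variance and ordered vehicle, low dose and high dose arrays within each BeadChip that held them. The second component (27.1%) set the arrays of BeadChip 4 apart. High dose array 3 stood alone on the third component (8.39%).

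**Figure D1:**
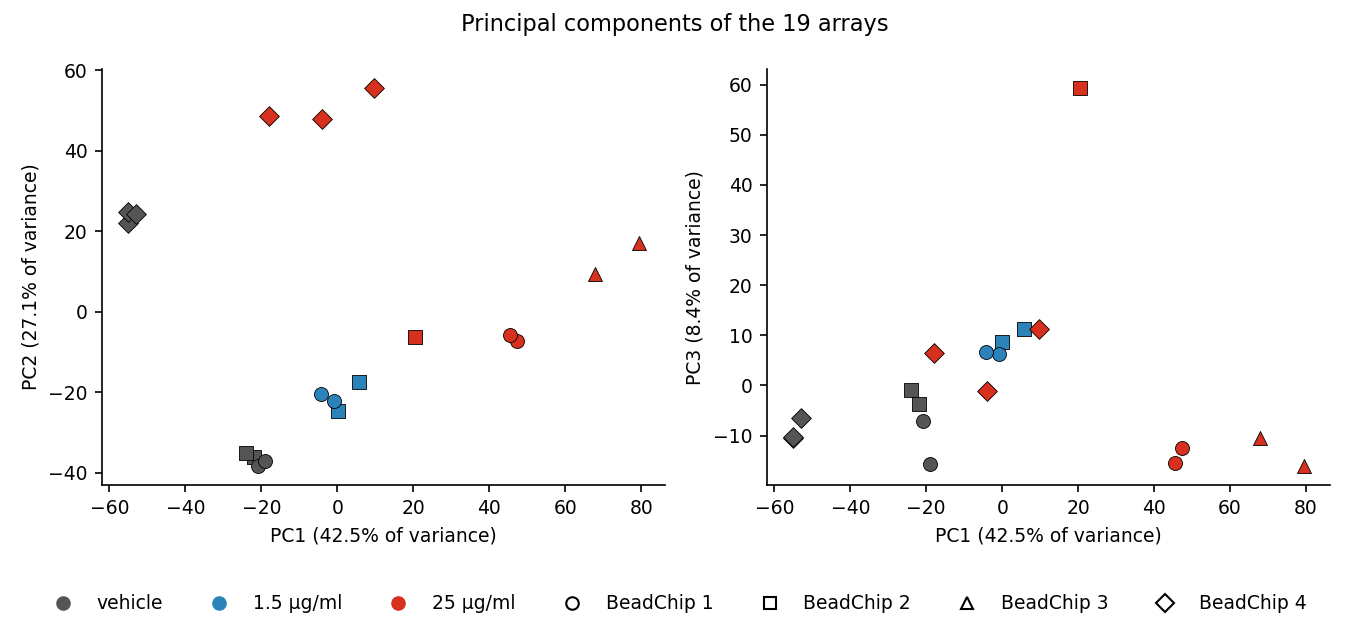
Scores of the 19 arrays on the first 3 principal components of normalized log2 signal, with colour for the treatment and marker shape for the BeadChip; the percentages on the axes are shares of the variance. High dose array 3 has a score of 59.3 on the third component, while the other 18 arrays lie between -16.1 and 11.3.

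The comparison of the high dose with vehicle asked which transcripts changed within 60 minutes of 25 µg/ml sanguinarine. Among genes with an established name, the largest rises were those of Zxda, a zinc finger gene (log2 fold change 3.56 ± 0.22 SE, 11.8-fold, adjusted p = 1.26e-09), and Prf1, which encodes the pore-forming protein perforin (3.37 ± 0.26, adjusted p = 1.7e-08). Enah, a regulator of actin filament assembly (3.23 ± 0.29), and the rhomboid protease gene Rhbdl2 (3.22 ± 0.21) rose by similar amounts. The largest falls given here, among genes with an established name, were those of the mitotic kinesin Kif23 (-1.93 ± 0.17, adjusted p = 1e-07), Tmx2 (-1.91 ± 0.21) and the histone-binding protein gene Rbbp7 (-1.91 ± 0.24). Tsc22d1 (-1.82 ± 0.23), the fatty acid oxidation enzyme gene Acadl (-1.77 ± 0.16) and the ubiquitin ligase gene Rnf13 (-1.75 ± 0.15) followed. Each of these genes moved the same way on the 3 BeadChips that held both groups, as the rule that picked them required. A second, dimmer probe did not pass for Tmx2 (0.21) or Acadl (0.07), and the 2 other probes of Enah lay at 0.42 and 0.25. A dim Tsc22d1 probe, the only described one, lay at -0.39. The 2 other probes of Kif23 lay at -0.37 and -0.11 and did not pass. Of the 44 named genes called here with several probes, 25 had a probe that did not pass and 8 a probe called in the opposite direction. The other 6 of the 10 largest rises carried only clone or predicted-gene names.

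In all, 6660 of 14525 genes changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 3587 of them higher and 3073 lower. Of these, 974 changed at least 2-fold, 622 higher and 352 lower. These directions are relative to arrays brought to one signal distribution. With arrays scaled to a common median in place of quantile normalization, the median gene lay at -0.23 and the split was 1472 higher and 5785 lower.

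The counts of gene lists called are not distinguished from chance. Of 100 divisions of the arrays into groups of the same sizes, the real one included, 60 gave as many lists at the high dose. As many were given by 11 of 100 at the low dose and 12 of 100 between the doses. The list of sarcomere and skeletal muscle genes passed upward. Of 20 measured sarcomere and skeletal muscle genes, 10 rose and none fell (11 and none adjusted over the list alone; median log2 fold change 0.42; camera adjusted p = 0.00472). The adjusted p was 0.453 with an estimated correlation. The median was 0.10 with median scaling and 0.02 without scaling, so the list rose mainly relative to the other genes. The giant sarcomere protein gene Ttn rose by 1.90 ± 0.15 (3 of its 4 probes rose and a dim one lay at 0.09) and the slow troponin gene Tnnt1 by 1.11 ± 0.18. Of 17 cardiomyocyte markers, 6 rose and 2 fell (camera adjusted p = 0.819): Mybpc3, a thick filament protein gene, rose by 0.85 ± 0.09, and Myh7, the slow myosin heavy chain gene, fell by 1.24 ± 0.14, while its 2 other, dimmer probes did not pass (both at -0.22). The skeletal actin gene Acta1 (0.33 ± 0.23, adjusted p = 0.275) and the myogenic regulator gene Myog (-0.06 ± 0.13, adjusted p = 0.743) did not pass, and Acta1 lay at -0.06 without high dose array 3.

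The list of cell cycle genes passed downward. Of 22 measured, 12 fell and none rose (14 and none adjusted over the list alone; median -0.36; camera adjusted p = 0.00344). The adjusted p was 0.453 with an estimated correlation. The median was -0.78 with median scaling, and -0.19 on BeadChip 4 alone, where the call was lost (adjusted p = 0.122). Ccnb1, the mitotic cyclin B1 gene, fell by 0.92 ± 0.12 and the thymidylate synthase gene Tyms by 0.79 ± 0.19 (by 0.46 without high dose array 3). A dim Tyms probe did not pass (0.02).

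Among 22 immediate early genes, which respond to stimuli without new protein synthesis, 9 fell and none rose (9 and none adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0742). Klf2 fell by 1.02 ± 0.17, Jun by 0.89 ± 0.14, Fos by 0.85 ± 0.30 (adjusted p = 0.0264), Atf3 by 0.85 ± 0.17 and Egr1 by 0.62 ± 0.16 (by 0.41 without high dose array 3). Myc was above background on 5 of 7 vehicle, 1 of 4 low dose and 1 of 8 high dose arrays, so the size of its fall (-0.40 ± 0.15, adjusted p = 0.0371) is not exact. The call for Fos was lost without any one of vehicle arrays 3 and 4 and high dose arrays 1, 2 and 7, with adjusted p up to 0.0784. That for Myc was lost without any one of 8 arrays, vehicle 1, 4, 5 and 6 and high dose 1, 2, 6 and 7, with adjusted p up to 0.0931. The MAP kinase phosphatase gene Dusp1 fell by 0.62 ± 0.10.

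Stress genes moved in both directions, and none of the lists in this paragraph passed camera. Of all genes tested, 45.9% were called at the high dose, so many called members are found in any list. The counts here and in the next paragraph are to be read beside that share. Of 20 targets of the integrated stress response, 9 rose and 1 fell (median 0.23; camera adjusted p = 0.0736). The median was -0.16 with median scaling and -0.24 without scaling, where the median gene lay at -0.23 and -0.31. Nupr1 rose by 1.08 ± 0.31, Ddit4 by 0.95 ± 0.23 and Ddit3, which encodes the transcription factor CHOP, by 0.64 ± 0.14, while Phgdh, an enzyme of serine synthesis, fell by 1.28 ± 0.16. The 3 rises lost their calls under 3, 2 and 3 alternatives in turn, with lowest values of 0.24 and 0.16 on BeadChip 4 alone for Nupr1 and Ddit4 and 0.12 without scaling for Ddit3. Without high dose array 3, Nupr1 rose by 0.56 and Ddit3 by 0.41. The second Phgdh probe did not pass (0.15). Of 16 genes of the unfolded protein response of the endoplasmic reticulum, 8 fell and none rose (camera adjusted p = 0.0592), among them the chaperone genes Calr (-0.99 ± 0.17) and Sdf2l1 (-0.98 ± 0.12). Of 22 heat shock factor 1 targets, 9 fell and 1 rose (camera adjusted p = 0.0736), with Ahsa1 at -0.47 ± 0.10 and Ubb at -0.42 ± 0.10. The inducible heat shock genes Hspa1a (-0.32 ± 0.40, adjusted p = 0.536) and Hspa1b (-0.50 ± 0.27, adjusted p = 0.131) did not pass, and without high dose array 3 they lay at 0.38 and -0.08. Of 24 NRF2 targets, 3 rose and 5 fell (camera adjusted p = 0.815). The haem oxygenase gene Hmox1 fell by 0.56 ± 0.10 and the catalase gene Cat by 0.73 ± 0.12.

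Of 20 p53 targets, 8 fell and 2 rose (camera adjusted p = 0.0644). The death receptor gene Tnfrsf10b fell by 1.39 ± 0.20 and Pmaip1 by 1.03 ± 0.12, while Bbc3 rose by 0.58 ± 0.10. The 2 other, dimmer probes of Tnfrsf10b (-0.09 and -0.01) and of Bbc3 (0.08 and 0.09) did not pass. Cdkn1a, the p21 gene, was at -0.13 ± 0.09 (adjusted p = 0.265), while a second Cdkn1a probe rose by 0.31. Of 21 apoptosis regulators, 7 rose and 5 fell (camera adjusted p = 0.815), and the anti-apoptotic gene Bcl2l1 fell by 0.99 ± 0.16. Of 19 sodium pump and calcium handling genes, 6 rose and 4 fell (camera adjusted p = 0.801). The calcium store protein gene Casq1 fell by 1.45 ± 0.20 and the calcium pump gene Atp2b1 by 1.42 ± 0.12. Of 17 cholesterol synthesis genes, 4 rose and 6 fell (camera adjusted p = 0.408). Nsdhl fell by 1.45 ± 0.16 and Cyp51 by 1.26 ± 0.08. The ubiquitin-conjugating enzyme gene Ube2d3 fell by 1.63 ± 0.12, and its 2 other probes lay at -0.84 and, without passing, at -0.10. A dimmer probe of Nsdhl did not pass (-0.02). The chemokine gene Ccl7 fell by 1.19 ± 0.16 and the intermediate filament gene Vim by 0.81 ± 0.13. The NF-kappaB inhibitor gene Nfkbia (-0.13 ± 0.10, adjusted p = 0.291; a dimmer probe rose by 0.40), Txnip (-0.04 ± 0.16, adjusted p = 0.866; -0.32 and past the threshold without high dose array 3, adjusted p = 0.0046) and the glycolytic enzyme gene Gapdh (0.07 ± 0.09, adjusted p = 0.536) did not pass. Gapdh lay at -0.06 without any scaling between arrays. Of the genes given here, those above background on only some of the 8 high dose arrays were Nsdhl (7), Atp2b1, Casq1 and Pmaip1 (6 each), Bcl2l1 (5), Ccl7 (4), Myog (4, and 5 of 7 vehicle arrays) and Hspa1b (3, and 4 of 7 vehicle arrays).

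**Figure D2:**
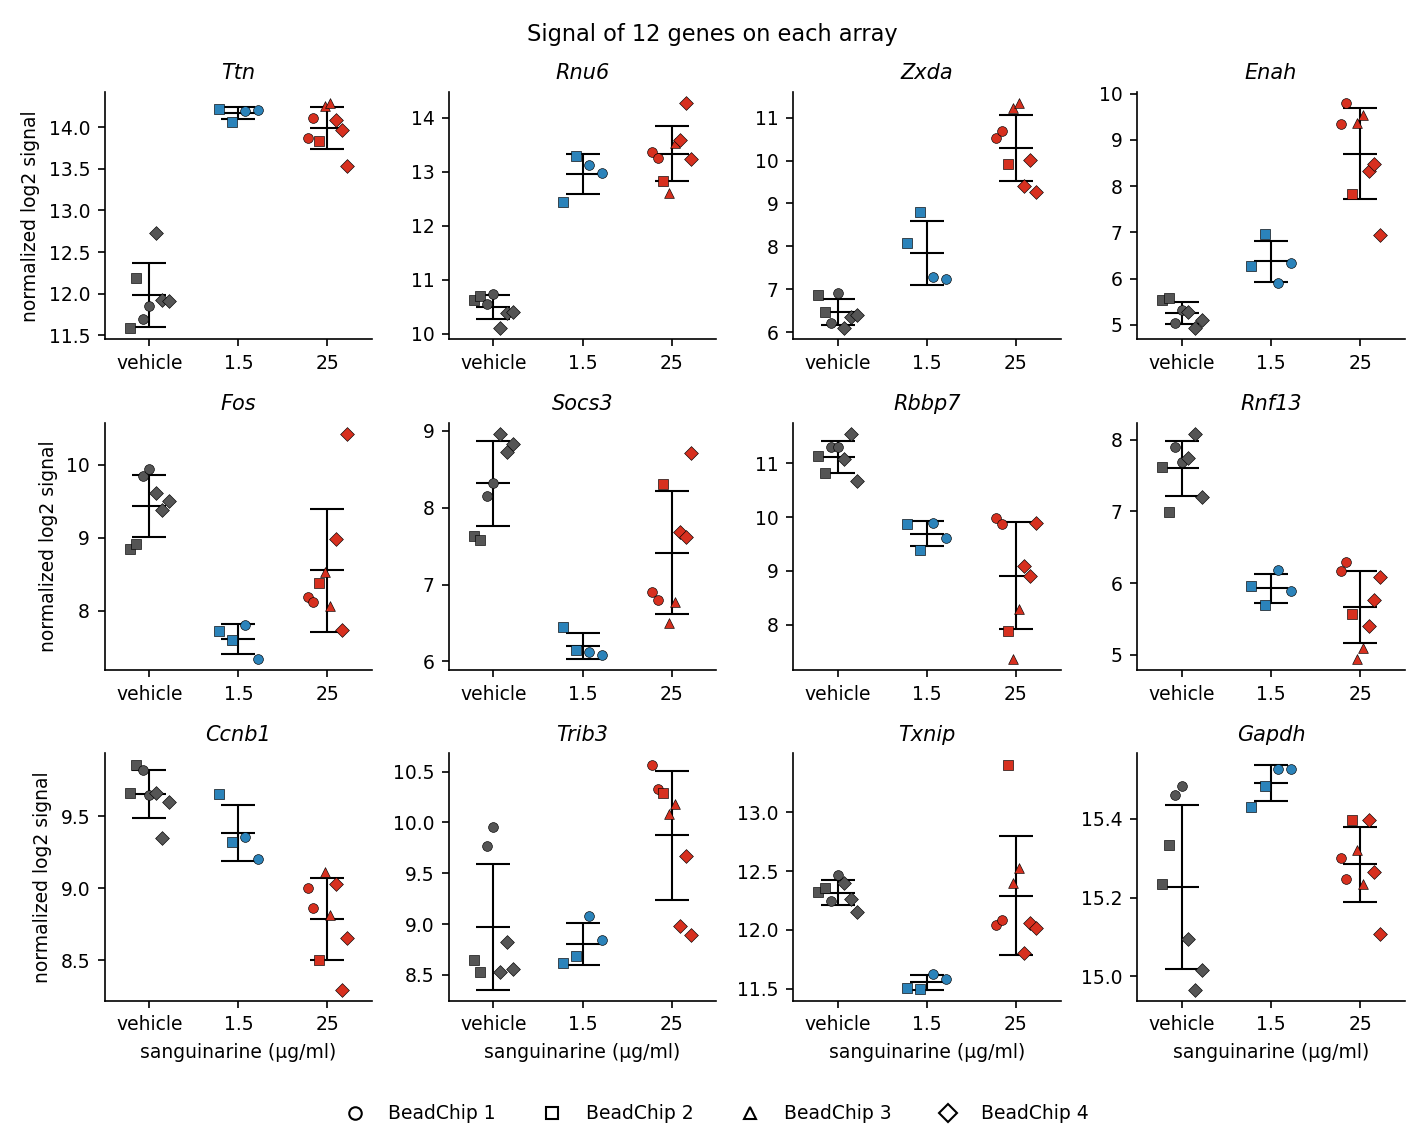
Normalized log2 signal of 12 genes on each of the 19 arrays; points are arrays with marker shape for the BeadChip, and bars show the mean and SD of each group (n = 7, 4 and 8). Ttn and Rnu6 are higher at both doses, and Rbbp7 and Rnf13 lower at both, without overlap with vehicle.

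The low dose was set against vehicle to ask which changes occurred at 1.5 µg/ml. Of the largest rises, those with an established name were Rnu6, the U6 small nuclear RNA of the spliceosome (log2 fold change 2.49 ± 0.24, 5.62-fold, adjusted p = 8.92e-06), and Ttn (2.25 ± 0.18, 4.77-fold, adjusted p = 1.26e-06). The largest falls given here, among genes with an established name, were those of the cytokine signalling inhibitor gene Socs3 (-1.78 ± 0.27, adjusted p = 0.000353), Rnf13 (-1.68 ± 0.18), Fos (-1.62 ± 0.36, adjusted p = 0.00615), Rbbp7 (-1.41 ± 0.29) and the dynactin subunit gene Dctn1 (-1.37 ± 0.20). Nsdhl (-1.32 ± 0.19), the actin-severing protein gene Gsn (-1.32 ± 0.25), Itm2a (-1.31 ± 0.17) and Tom1 (-1.31 ± 0.18) came next. All of these moved the same way on both BeadChips that held low dose arrays, as the rule that picked them required. Other probes did not pass for Tom1 (-0.21 and -0.07), Rbbp7 (-0.22), Nsdhl (-0.14) and a dim one for Ttn (-0.32). Of the 18 named genes called here with several probes, 16 had a probe that did not pass. In all, 1806 genes changed, 1023 higher and 783 lower, and 149 changed at least 2-fold, 92 higher and 57 lower. The split was 890 higher and 428 lower with median scaling. The count fell to 1166, 1047 and 1184 without low dose arrays 2, 3 and 4 in turn, and to 619 with the replicate number as a block in place of the BeadChip.

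At the low dose too, the list of sarcomere and skeletal muscle genes passed upward: 6 of 20 rose and none fell (6 and none adjusted over the list alone; median 0.37; camera adjusted p = 7.64e-05, and adjusted p = 0.159 with an estimated correlation). Myh8, the perinatal myosin heavy chain gene, rose by 1.26 ± 0.13. Mybpc3 rose by 1.10 ± 0.11 and Smtn, a smooth muscle cytoskeletal gene, by 0.95 ± 0.14. Other probes did not pass for Myh8 (0.18 and 0.24) and Smtn (0.03), and 2 dimmer probes of Myh7 rose (0.83 and 0.91) although its brightest did not pass (-0.14). Other muscle lists passed fry but not camera: of 17 cardiomyocyte markers 4 rose and none fell (median 0.06; camera adjusted p = 0.121, fry adjusted p = 0.000905), and of 10 smooth muscle markers 1 rose and 1 fell (median 0.21; camera adjusted p = 0.216, fry adjusted p = 0.00014). Acta1 was at 0.25 ± 0.28 (adjusted p = 0.646) and Myog at -0.13 ± 0.15 (adjusted p = 0.67). Of 22 immediate early genes, 6 fell and none rose (6 and none adjusted over the list alone; median -0.31; camera adjusted p = 0.00505, and adjusted p = 0.272 with an estimated correlation and 0.0547 with described probes only). Besides Fos, Klf2 fell by 1.03 ± 0.20 and Egr1 by 0.97 ± 0.19. Atf3 (-0.53 ± 0.21, adjusted p = 0.106) and Myc (-0.35 ± 0.18, adjusted p = 0.235) did not pass, but Atf3 fell by 0.62 (adjusted p = 0.009) without high dose array 3. Dusp1 fell by 0.76 ± 0.12 and Tob1, an antiproliferative gene, by 1.15 ± 0.15, while the circadian gene Per1 rose by 0.82 ± 0.12 (a dim Per1 probe lay at 0.23 without passing).

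Of 16 glycolysis genes, 3 rose and none fell (3 and none adjusted over the list alone; median 0.21; camera adjusted p = 0.00644, and adjusted p = 0.519 with an estimated correlation). Pkm rose by 0.70 ± 0.14 and Aldoa by 0.52 ± 0.10. A dimmer Pkm probe did not pass (0.34). The glycolysis call was also lost without the BeadChip term (adjusted p = 0.114), with every probe on its own (0.0676), on BeadChip 2 alone (0.338) and with described probes only (0.249). The median of the glycolysis list then lay from 0.14 to 0.21. Gapdh was at 0.17 ± 0.10 (adjusted p = 0.31). Of 20 p53 targets, 3 fell and none rose (5 and none adjusted over the list alone; median -0.20; camera adjusted p = 0.0211, and adjusted p = 0.421 with an estimated correlation). Polk fell by 0.75 ± 0.13 and Gadd45a by 0.62 ± 0.15, and Cdkn1a was at -0.20 ± 0.11 (adjusted p = 0.264). The p53 call was lost without low dose array 2 (adjusted p = 0.0503), with only the arrays of BeadChips 1 and 2 (0.116), on BeadChip 1 (0.0706) or 2 (0.0951) alone and with described probes only (0.171). The median of the p53 list then lay from -0.21 to -0.14. Txnip, which encodes a thioredoxin-binding protein, fell by 0.90 ± 0.19 (adjusted p = 0.00512). Atp2b1 fell by 1.06 ± 0.14 and Ube2d3 by 1.10 ± 0.15, whose 2 other probes did not pass (-0.39 and -0.06). Hmox1 (-0.23 ± 0.12, adjusted p = 0.243), Hspa1a (0.52 ± 0.47, adjusted p = 0.549), Hspa1b (0.16 ± 0.32, adjusted p = 0.808), Ddit3 (0.10 ± 0.17, adjusted p = 0.769) and Nfkbia (0.30 ± 0.12, adjusted p = 0.114) did not pass.

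**Figure D3:**
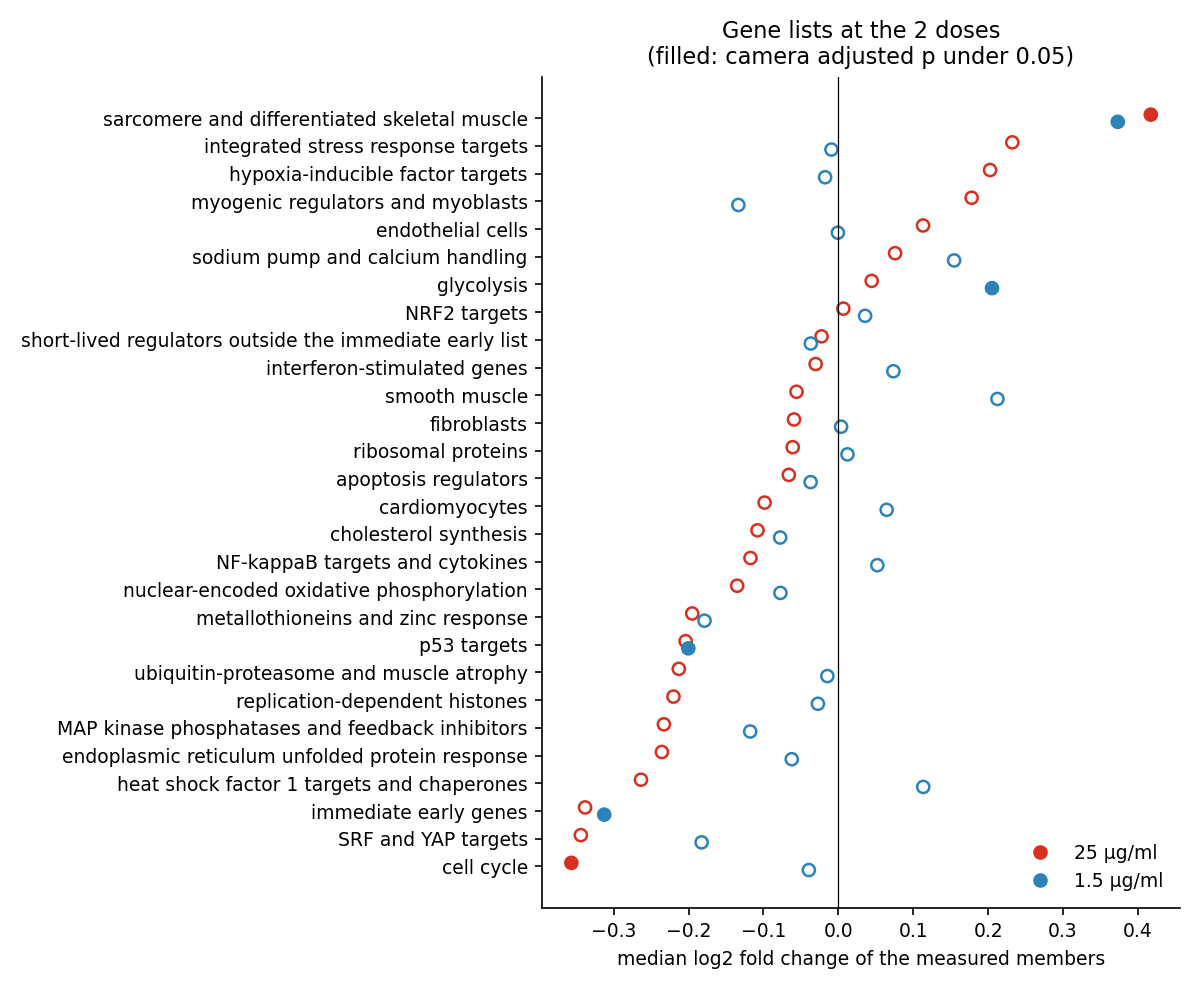
Median log2 fold change of the measured members of 28 gene lists at each dose against vehicle; each point is a list at one dose, and filled points passed camera at an adjusted p under 0.05. The sarcomere list lies at 0.42 at the high dose and 0.37 at the low dose, and the cell cycle list at -0.36 and -0.04.

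The high and low doses were also set against each other, which tests whether their effects differed. Zxda (log2 fold change 2.43 ± 0.28, adjusted p = 3.61e-05), Prf1 (2.41 ± 0.32, adjusted p = 0.000203) and Enah (2.38 ± 0.37, adjusted p = 0.000597) were higher at the high dose. The 2 other probes of Enah did not differ (-0.08 and -0.17). The largest falls among named genes were those of the transcriptional cofactor gene Vgll3 (-1.40 ± 0.25, adjusted p = 0.0018), the antigen-processing gene Tapbp (-1.30 ± 0.24) and the transferrin receptor gene Tfrc (-1.25 ± 0.26). Vgll3 lay at 0.15 without the BeadChip term, and second probes of Vgll3 (-0.12) and Tapbp (-0.30) did not pass. Tapbp lay at -0.42 on BeadChip 2 alone, whose only high dose array is array 3, and at -1.57 without that array. Vgll3 was above background on 6 of the 8 high dose arrays and Tapbp on 4. Tfrc, for which high dose array 3 was the lowest, lay at -0.79 without that array. On BeadChip 2 alone, where that array is the only high dose array, Tfrc lay at -2.44. Of the 28 named genes called here with several probes, 21 had a probe that did not pass. In all, 2514 genes differed, 1271 higher and 1243 lower at the high dose, and 288 differed at least 2-fold, 262 higher and 26 lower. With median scaling the median gene lay at -0.30 and 5296 genes differed, 369 higher and 4927 lower. With cyclic loess the split was 1530 higher and 828 lower, and with described probes only it was 437 higher and 609 lower. Of the 355 probes at least 2-fold higher at the high than at the low dose, 86.2% had no transcript description. The share was 48.2% of the 56 probes at least 2-fold lower and 52.9% of all probes.

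Of 20 integrated stress response targets, 8 were higher and none lower at the high dose (12 and 2 adjusted over the list alone; median 0.32; camera adjusted p = 0.00245, and adjusted p = 0.365 with an estimated correlation). The median was -0.10 with median scaling and -0.19 without scaling, and the call was then lost (adjusted p = 0.0768 and 0.0588). Nupr1 was higher by 1.37 ± 0.39 and Trib3, which encodes a pseudokinase, by 1.34 ± 0.21, with 2 dimmer Trib3 probes at 0.34 and 0.18 that did not pass. Ddit3 was higher by 0.54 ± 0.18 (adjusted p = 0.0472), but lay at -0.02 without scaling between arrays, and its call was lost without any one of 13 arrays (adjusted p up to 0.161). The call for Nupr1 was lost without low dose array 1 or 2 (adjusted p up to 0.0579), and it was higher by 0.65 without high dose array 3. The list of cell cycle genes passed downward: 8 of 22 fell and none rose (14 and none adjusted over the list alone; median -0.44; camera adjusted p = 4.21e-05, and adjusted p = 0.365 with an estimated correlation). Top2a was lower (-0.89 ± 0.17), although a dimmer Top2a probe lay at 0.67 without passing, and Mcm2 was lower too (-0.83 ± 0.13).

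Of 22 heat shock factor 1 targets, 5 were lower and none higher (8 and none adjusted over the list alone; median -0.30; camera adjusted p = 0.0019, and adjusted p = 0.365 with an estimated correlation), among them the co-chaperone genes Ahsa1 (-0.66 ± 0.13) and Stip1 (-0.64 ± 0.11). Of 16 unfolded protein response genes, 7 were lower and 1 higher (9 and 1 adjusted over the list alone; median -0.33; camera adjusted p = 0.016, and adjusted p = 0.365 with an estimated correlation). Calr (-0.70 ± 0.22, adjusted p = 0.0321) and Sdf2l1 (-0.66 ± 0.15) were lower (the call for Calr was lost without any one low dose array or high dose array 1 or 3, adjusted p up to 0.109), and Herpud1, which takes part in the degradation of misfolded proteins, was higher (0.54 ± 0.13), while its second probe did not pass (0.04). Of 17 ubiquitin and proteasome genes, 5 were lower and none higher (6 and 1 adjusted over the list alone; median -0.27; camera adjusted p = 0.0402, and adjusted p = 0.365 with an estimated correlation), with the proteasome subunit gene Psmd12 at -0.67 ± 0.11 and Ube2d3 at -0.52 ± 0.15. Other probes of Psmd12 (-0.23) and Ube2d3 (-0.05) did not pass. The call for Ube2d3 was lost without low dose array 1 or 3 or high dose array 1 (adjusted p up to 0.0858). The replication-dependent histone list was called lower although none of its 18 measured members passed alone (median -0.28; camera adjusted p = 0.0402, and adjusted p = 0.773 with an estimated correlation). Without high dose array 3, only the integrated stress response call was left of these 6, and it was itself lost with every probe on its own (median 0.15, adjusted p = 0.167). The median was then -0.18 (adjusted p = 0.0866) for heat shock factor 1 targets, -0.26 (0.0549) for the cell cycle and -0.12 (0.53) for histones. It was -0.28 both for the unfolded protein response (adjusted p = 0.113) and for ubiquitin and proteasome genes (0.067). With described probes only, these lists lay at -0.08 (adjusted p = 0.786) and -0.10 (0.385), and with every probe on its own at -0.26 (0.112) and -0.17 (0.487), so both calls depend on the choice of probes. The histone call was also lost without low dose array 2 (0.12) or high dose array 1 (0.0607) or 6 (0.0852), and the proteasome call without low dose array 1 (0.0595) or 4 (0.101) or high dose array 1 (0.0607).

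Some genes that changed at the low dose lay closer to vehicle at the high dose. Socs3 was higher at the high than at the low dose by 1.10 ± 0.28 (adjusted p = 0.0132) and Txnip by 0.86 ± 0.20 (adjusted p = 0.00942), both having fallen at the low dose. High dose array 3 carried much of this: without it Socs3 was higher by 0.69 (adjusted p = 0.0392) and Txnip by 0.48 (adjusted p = 0.00542). The calls of both were lost with median scaling and without scaling, where Txnip lay as low as 0.36 and Socs3 at 0.64. Of genes that did not pass at the low dose, Myh7 (-1.10 ± 0.18) and Nfkbia (-0.43 ± 0.13, adjusted p = 0.0251) were lower at the high than at the low dose, and a dimmer Nfkbia probe did not pass (0.10). The call for Nfkbia was lost without low dose array 3 or 4 or high dose array 2 (adjusted p up to 0.111). Of the 1806 genes changed at the low dose, 142 differed between the doses in the direction back toward or past vehicle. Another 290 differed in the direction away from it. The distance from vehicle itself was not tested. These genes, Socs3 and Txnip included, were picked on the same low dose arrays, which by itself favours differences back toward vehicle. The 142 therefore cannot be taken as a count of changes undone at the high dose.

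The 2 doses were compared across genes. Of the 1806 genes changed at the low dose, 1517 (84.0%) changed in the same direction at the high dose, 822 higher and 695 lower. Independent lists of these sizes would share 253 and 166 genes. The log2 fold changes of the 2 doses had a Pearson's r of 0.707 and a Spearman's rho of 0.638 across 14525 genes, which are not independent replicates. Both comparisons use the same vehicle arrays. In 100 simulations with no effect of either dose, r had a mean of 0.342 and a range from -0.23 to 0.844. The observed covariance was 0.127 against a mean of 0.00609 in the simulations, a difference of 0.121. The simulations called no gene the same way at both doses. With separate vehicle arrays for each dose, r was 0.748 and 0.701 in the 2 divisions of the vehicle arrays tried, the covariance 0.130 and 0.129, and the shared changes 758 higher and 553 lower, and 677 higher and 502 lower.

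**Figure D4:**
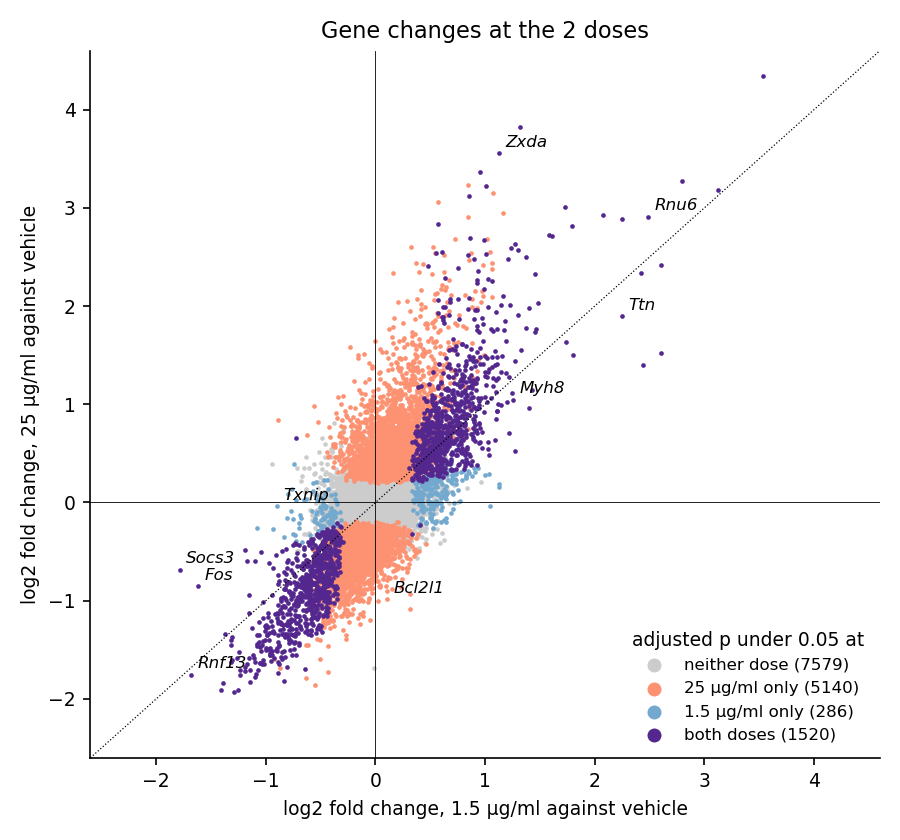
Log2 fold change against vehicle at 1.5 µg/ml (x axis) and 25 µg/ml (y axis) for 14525 genes; each point is a gene, coloured by the dose at which its adjusted p is under 0.05, and the dotted line marks equal change. Ttn lies near 2 at both doses, and Zxda rises by 3.56 at the high dose.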

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

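The tests of single arrays and of probe descriptions in this part were planned only after the results they concern had been seen, except the tests of scaling and of signal for the probe descriptions and the divisions of the arrays without regard to BeadChips.

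Dividing the arrays of each comparison into other groups of the same sizes tested whether the counts of changed genes could arise by chance. For the high dose against vehicle, 1 of 100 divisions, the real one, gave as many as 6660 genes, and the highest other gave 5165, so chance is excluded. That other division was nearly the real one turned round: its larger group held 6 of the 7 vehicle arrays and 2 of the 8 high dose arrays. For the low dose against vehicle, 2 of 100 divisions, the real one included, gave as many as 1806 genes, which excludes chance under these divisions. They cross BeadChips: the other gave 2099 and set vehicle arrays 1 and 2 and low dose arrays 1 and 2, all on BeadChip 2, against the rest. With arrays exchanged within BeadChips only, a test chosen afterwards, 1 of 36 arrangements, the real one, gave as many and the highest other gave 331. Within BeadChips the low dose changed 525 genes on BeadChip 1 and 1373 on BeadChip 2. For the high against the low dose, 1 of 100, the real one, gave as many as 2514 and the highest other gave 1286. These divisions cross BeadChips too. Within BeadChips 1 of 360 arrangements gave as many genes at the high dose against vehicle (highest other 5165). Between the doses the 18 arrangements are too few for a share under 0.05 (real 2514, highest other 537), so chance is not excluded there. All of these divisions treat the arrays as independent, although the experiment of each is not given. For the gene lists chance is not excluded. At the high dose against vehicle 60 of 100 divisions gave as many as 2 lists (highest other 12), at the low dose 11 of 100 gave as many as 4 (highest other 5), and between the doses 12 of 100 gave as many as 6 (highest other 10).

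High dose array 3 stood apart from the other high dose arrays. Its score on the third principal component was 59.3, while the other high dose arrays lay between -16.1 and 11.3, a gap of 0.637 of the group's range. It was also the lowest high dose array for Jun (gap 0.596), Atf3 (0.652), Tfrc (0.637), Slc30a1 (0.605), Nfkbiz (0.673), Slc2a1 (0.662) and Irf1 (0.541), and the highest for Tnnt1 (0.561), Txnip (0.547) and Des (0.559). Without this array, 9 of the 103 named genes called at the high dose against vehicle and 17 of the 60 called between the doses moved less by over 1.5 times, and 7 and 16 lost their calls. A difference of BeadChip 2 is argued against, since the farthest other array of BeadChip 2 had a score of 11.2. A low dose array with a wrong label stays open. The first test set for this was the array's position between its low dose neighbours (0) and the effect of the other high dose arrays (1). High dose arrays 1 and 2 lay at 1.15 and 1.18. They share BeadChip 1, so each kept a high dose neighbour in its fit, which array 3 lacked, and are not like references. At 0.253, array 3 came out on the side of a wrong label. A count of genes was added after that value had been seen: 3158 genes differed between it and the low dose arrays, while 0 differed between any single low dose array and the other 3 (limma, adjusted p under 0.05), and 2802 differed between it and the other high dose arrays. These counts rest on 1 array and show that it resembled neither group, which does not settle its label. A culture that responded differently and a fault in handling the sample stay open too, untested.

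Probes without a transcript description rose more than described probes. At the high dose they were 72.7% of the 887 probes that rose at least 2-fold, 49.8% of the 891 that fell and 52.9% of all 21302. In 725 genes with 1 probe of each kind at a similar signal, the probe without a description lay above the described one by a median of 0.04 (bootstrap interval of the median 0.0199 to 0.0778), so the difference within genes was small. Without scaling between arrays the median was 0.0401 (interval 0.0244 to 0.0645), so the difference within these pairs was also present without scaling. Scaling moves probes of similar signal nearly alike, so these pairs cannot decide whether it caused the shares above. The shares were not computed without scaling. These intervals resampled gene pairs on the same arrays and do not measure the spread between arrays. They therefore cannot decide whether the lower signal of the high dose arrays played a part. At the low dose the median was 0.0218 (interval 0.000927 to 0.046, its lower end close to 0). There the mean signal was 0.984 times that of vehicle, 0.902 on BeadChip 1 and 1.08 on BeadChip 2, and on BeadChip 2 alone, a test chosen afterwards, the median was 0.0406 (interval 0.00829 to 0.0669). A larger part of nuclear or unspliced RNA may be involved but is undecided. With all 8 measured nuclear noncoding RNAs, the share of random lists with as large a median was 0.0002, but the rise of Rnu6 and Meg3 had been seen before the list was written. They were left out after that share had been seen, and for the 6 others, which moved in both directions, the share was 0.11.

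In 492 groups of values an array stood apart 28 times from the rest of its group, where chance alone flags about 1 group in 20. Besides high dose array 3, these are, with the gap as a share of the group's range, vehicle 4 for Cyp51 (0.595) and Dusp7 (0.583), vehicle 5 for Mx2 (0.85) and vehicle 7 for Casq1 (0.631). In the low dose group they are array 1 for the number of probes detected (19126 against 18243 to 18335, gap 0.896), Socs3 (0.844) and Myl9 (0.878), array 2 for Bbc3 (0.852), Bax (0.848) and Myc (0.979), and array 3 for Egln3 (0.843). In the high dose group they are array 8 for Fos (0.537) and Phgdh (0.562), array 6 for Ddit4 (0.599) and Top2a (0.582), array 5 for Myc (0.613) and array 2 for Tob1 (0.557).

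The effect of the high dose differed between BeadChip 4 and BeadChips 1 and 2 for 24 genes by an interaction test (limma, adjusted p under 0.05), of which 12 had opposite signs. Across genes the effects had an r of 0.767. Of the 6660 genes changed at the high dose, 5958 had the same sign on every BeadChip that held both groups, a count that the choice of genes on the same arrays raises.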

How the results depend on the processing

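The alternatives without scaling between arrays, without BeadChip 3 and high dose array 3, and with described probes only were chosen after seeing the data. The cause of each difference was not tested unless the alternative's own construction shows it. Genes changed at the high dose numbered 6660 and stayed within 1.5 times of that except with every probe on its own (10233 probes, from 21302 tested), BeadChip 4 alone (4050, fewer arrays) and described probes only (3112, fewer genes). Without BeadChip 3 and high dose array 3 the count was 7050. Leaving out 1 array gave 6076 to 6966. Genes changed at the low dose numbered 1806, and 3078 with every probe on its own, 630 without the BeadChip term, 525 on BeadChip 1 alone, 3628 with only the 2 groups compared, 4166 with array quality weights, 732 at an adjusted p under 0.01 and 955 with described probes only. They were 2642 without BeadChip 3 and high dose array 3, and 1047 (without low dose array 3) to 2531 (without high dose array 3) with 1 array left out. Genes that differed between the doses numbered 2514, and 5296 with median scaling, 6462 without scaling, 3966 with every probe on its own, 4054 on BeadChip 1 alone, 4528 on BeadChip 2 alone, 787 at an adjusted p under 0.01 and 1046 with described probes only. With 1 array left out they were 1211 to 3058, and fell by more than 1.5 times without low dose arrays 3 (1239) and 4 (1211) and high dose arrays 1 (1518) and 2 (1651). Without any scaling the median gene lay at -0.31 at the high dose against vehicle and at -0.38 against the low dose, and the calls split 1150 higher and 6745 lower, and 272 higher and 6190 lower.

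Lists changed at the high dose numbered 2, and 4 with cyclic loess, the random block, BeadChips 1 and 2 only and described probes only. They numbered 5 with maximum likelihood normexp, no background correction, the authors' values, no BeadChip term and the intensity trend. BeadChip 2 alone, with array 3 as its only high dose array, is left out of these counts. Lists changed at the high dose numbered 7 with median scaling and without scaling, 11 without a filter, 15 with fry and 0 with an estimated correlation. With 1 array left out they were 2 to 9, with 4 without high dose array 6 and 9 without high dose array 8. At the low dose they numbered 4, and 2 on BeadChip 2 alone, 1 with described probes only and 0 with an estimated correlation, and 3 to 4 with 1 array left out. Between the doses they numbered 6, and 2 with every probe on its own, 3 on BeadChip 1 alone and with array weights, 11 with fry, 0 with an estimated correlation and 1 without BeadChip 3 and high dose array 3. With 1 array left out they were 1 (without high dose array 3) to 7. The integrated stress response list had a median of -0.10 between the doses with median scaling, where the median gene lay at -0.30, and the call was lost (adjusted p = 0.0768). Calls of lists were lost under 1 to 9 alternatives other than leaving out 1 array, an estimated correlation included: 9 each for histones and for ubiquitin and proteasome genes between the doses, 6 for the unfolded protein response between the doses, 5 each for glycolysis and p53 targets at the low dose, and 1 for the sarcomere list at either dose. The correlation of the doses was 0.707, with 0.644 to 0.726 when 1 array was left out. It was 0.535 on BeadChip 1 alone and 0.55 on BeadChip 2 alone, which held 1 high dose array.

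The replicate numbers were checked for pairing. Deviations of same-numbered arrays from their group means correlated at 0.05 to 0.317 for vehicle and low dose, -0.35 to 0.682 for vehicle and high dose and -0.08 to 0.05 for low and high dose. BeadChip differences were left in these deviations, and same-numbered arrays shared a BeadChip in 4 of 4, 2 of 7 and 0 of 4 pairs. The check therefore cannot decide whether the numbers pair the arrays, and they were not taken as pairs. The best match had the same number in 2 of 4, 2 of 7 and 0 of 4. With the replicate block in place of the BeadChip, the counts were 6873 genes at the high dose, 619 at the low dose and 2499 between them, with 6, 4 and 7 lists and a correlation of 0.72.

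Of the 246 gene results named, 30 had the opposite sign under at least 1 alternative, with 45 such values. Of these, 11 came with median scaling and 15 without scaling, where the median gene itself lay below 0, so they show the dependence on scaling. With median scaling these were Dusp7 -0.0224, Fkbp4 -0.19, Mafg -0.0961, Pgd -0.13, Bax -0.20, Sdhc -0.18, Fbln1 -0.034 and Egfl7 -0.0184 at the high dose against vehicle and Irf1 -0.0666, Mcl1 -0.0677 and Des -0.0104 between the doses. Without scaling these were Dusp7 -0.10, Fkbp4 -0.27, Mafg -0.18, Pgd -0.21, Bax -0.28, Sdhc -0.27, Rpl32 -0.0425, Rpl23 -0.0311, Fbln1 -0.12 and Egfl7 -0.10 at the high dose against vehicle and Irf1 -0.15, Pgam2 -0.0752, Mcl1 -0.15, Des -0.0976 and Ddit3 -0.0176 between the doses. Without the BeadChip term these were Atp5c1 0.0366 at the low dose against vehicle and Vgll3 0.15, Jun 0.0511 and Actg2 1.53 between the doses. On BeadChip 1 alone these were Dusp7 -0.0422 and Acta2 -0.0072 at the high dose against vehicle and Acta1 -0.57 between the doses. High dose values on BeadChip 2 alone rest on 1 high dose array, array 3. On it these were Fkbp4 -0.0879, Mafg -0.0358, Nfkbiz -0.34, Flna -0.17 and Txnip 1.06 at the high dose against vehicle. Between the doses they were Klf6 -0.12, Flt1 -0.29 and Egr1 -0.53. On BeadChip 4 alone these were Egln3 -0.0211 and Slc2a1 0.0207 at the high dose against vehicle. With described probes only these were Sox4 -0.0235 and Acta2 -0.13 at the high dose against vehicle. Apart from these, 146 results stayed the same there and 10 lost their call. Another 1 changed sign with neither value past the threshold. The remaining results had no described probe kept and were not tested there. A change of sign with neither value past the threshold was counted apart, 65 times. Among the 215 named gene results past the threshold, 61 lost their call without some 1 array, 15 at the high dose, 19 at the low dose and 27 between the doses, and 146 lost it or changed sign under at least 1 other alternative, subsets of the BeadChips included. Leaving out 1 array gave 4674 values over all 246 results, those that never passed and so could not lose a call included. Among these values calls were lost 366 times, most often without low dose arrays 3 (38) and 4 (38). The signal over background limits genes near the detection limit, whose fold changes are compressed.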

Other observations

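The values in this part were chosen after they had been seen, except those of the gene lists and of the genes picked by the fixed rule, both fixed before the data were examined. Nuclear noncoding RNAs moved in both directions. At the high dose Rnu6 rose by 2.91 ± 0.20 on the log2 scale (SE), Neat1, the scaffold of nuclear paraspeckles, by 2.33 ± 0.31, the imprinted antisense RNA Kcnq1ot1 by 2.16 ± 0.41 and Meg3 by 1.78 ± 0.29. Dleu2 fell by 0.68 ± 0.10, and Pvt1 was at -0.36 ± 0.16 (limma, adjusted p = 0.0792). Snhg12 rose by 0.30 ± 0.12 (adjusted p = 0.049), and Snhg11 did not pass (0.34 ± 0.14, adjusted p = 0.055). At the low dose Neat1 rose by 1.46 ± 0.37 (adjusted p = 0.0148) and Meg3 by 1.37 ± 0.35 (adjusted p = 0.0145). Of 7 measured transcripts of the mitochondrial genome, 5 rose at the high dose, from 0.27 ± 0.09 for mt-Cytb to 2.07 ± 0.46 for mt-Nd4l, with mt-Co2 at 1.34 ± 0.19, while mt-Nd5 and mt-Nd6 did not pass. None of the 7 passed at the low dose, where mt-Nd4 was nearest (0.30 ± 0.10, adjusted p = 0.05). The nuclear-encoded oxidative phosphorylation genes had 2 members higher and 9 lower of 22 at the high dose (median -0.14, camera adjusted p = 0.0597).

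The lists not described elsewhere gave these counts at the high dose. Of 13 MAP kinase phosphatases and feedback inhibitors, 1 rose and 5 fell (camera adjusted p = 0.124). Of 7 metallothionein and zinc response genes, 1 rose and 2 fell (0.644). Of 21 NF-kappaB targets and cytokines, 1 rose and 6 fell (0.133), and of 14 interferon-stimulated genes 3 rose and 3 fell (0.819). Of 14 hypoxia-inducible factor targets, 4 rose and 2 fell (0.815), and of 16 glycolysis genes 7 rose and 4 fell (0.815). Of 28 short-lived regulators outside the immediate early list, 5 rose and 7 fell (0.76), of 16 SRF and YAP targets 4 rose and 8 fell (0.133), and of 33 ribosomal protein genes 6 rose and 8 fell (0.644). Of 18 replication-dependent histones, none rose and 6 fell (0.0736), and of 17 ubiquitin, proteasome and muscle atrophy genes 1 rose and 6 fell (0.0597). Among cell types, 2 of 8 myogenic regulators rose and 2 fell (0.819), 2 of 10 smooth muscle markers rose and 2 fell (0.853), 1 of 11 fibroblast markers rose and 4 fell (0.746), and 1 of 6 endothelial markers rose (0.853). Of 4 leukocyte markers 1 rose, and of 3 adipocyte markers none passed; both lists were too short for the list test.

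The other genes picked by the fixed rule, each past the threshold (limma, Benjamini-Hochberg), are given here with their log2 fold changes and SE. At the high dose against vehicle the rises were Dusp7 0.41 ± 0.15, Fkbp4 0.26 ± 0.09, Mafg 0.35 ± 0.13, Pgd 0.33 ± 0.10, Hif3a 0.52 ± 0.17, Nfkbiz 0.66 ± 0.21, Stat2 0.63 ± 0.13, Mx2 0.59 ± 0.17, Bax 0.25 ± 0.09, Vegfa 0.88 ± 0.22, Egln3 0.62 ± 0.19, Pgam2 0.62 ± 0.11, Pkm 0.51 ± 0.12, Cox6c 0.52 ± 0.10, Sdhc 0.20 ± 0.08, Ccnl1 1.31 ± 0.21, Sox4 1.29 ± 0.20, Flna 1.07 ± 0.23, Crim1 0.40 ± 0.12, Mvd 0.77 ± 0.12, Rpl32 0.40 ± 0.09, Rpl23 0.37 ± 0.10, Ryr3 1.35 ± 0.24, Birc2 0.76 ± 0.11, Bik 0.66 ± 0.14, Psmd4 0.46 ± 0.09, Itga7 0.90 ± 0.18, Ryr2 0.68 ± 0.11, Smtn 1.04 ± 0.11, Acta2 0.27 ± 0.10, Fbln1 0.38 ± 0.11, Egfl7 0.38 ± 0.14 and Csf1r 0.49 ± 0.17. The falls there were Errfi1 -0.59 ± 0.13, Slc30a1 -0.75 ± 0.16, Slc30a5 -0.43 ± 0.09, Vcam1 -0.85 ± 0.19, Gbp2 -0.79 ± 0.13, Ifit2 -0.43 ± 0.14, Egln1 -1.13 ± 0.12, Slc2a1 -0.48 ± 0.17, Pfkp -1.12 ± 0.10, Hk1 -0.63 ± 0.17, Ndufs3 -0.78 ± 0.09, Tob1 -1.12 ± 0.13, Csrnp1 -0.85 ± 0.13, Thbs1 -1.15 ± 0.18, Ccn1 -0.74 ± 0.13, Rpl30 -0.87 ± 0.15, Rpl18 -0.64 ± 0.10, H2bc7 -0.74 ± 0.11, H2bc15 -0.68 ± 0.10, Psmd12 -0.68 ± 0.09, Mef2a -0.60 ± 0.14, Mef2d -0.54 ± 0.14, Nppb -0.65 ± 0.14, Actg2 -0.41 ± 0.13 and Fn1 -0.71 ± 0.17. Synpo2 was not above background on any high dose array and was at least 1.21-fold lower. Mef2a and Csf1r were above background on 7 of the 8 high dose arrays, Mef2d on 4, Actg2 on 3 (and 4 of 7 vehicle and 3 of 4 low dose arrays) and Mafk on 3 (6 of 7 and 3 of 4). Ryr3 was above background on 6 of 7 vehicle arrays, Lyz2 on 3 and Mx2 on 1, and Synpo2 on 6 of 7 vehicle and 2 of 4 low dose arrays. Another probe was called in the opposite direction at the high dose for Pkm, Pfkp, Crim1, Rpl23, Birc2, Smtn, Acta2 and Egfl7. At the low dose against vehicle the rises were Fkbp4 0.62 ± 0.11, Stip1 0.40 ± 0.11, Pgd 0.42 ± 0.12, Uqcrc1 0.37 ± 0.11, Ccnl1 0.79 ± 0.25, Flna 0.87 ± 0.28, Mvd 0.64 ± 0.15, Rpl22 0.40 ± 0.10, H3c1 0.94 ± 0.30, Orai1 0.65 ± 0.13, Itga7 0.83 ± 0.21, Gata4 0.88 ± 0.28 and Lyz2 0.57 ± 0.17. The falls there were Spred1 -0.55 ± 0.10, Phgdh -0.77 ± 0.19, Vldlr -0.48 ± 0.12, Ifit2 -0.55 ± 0.17, Cox5a -0.38 ± 0.11, Atp5c1 -0.32 ± 0.10, Ccn1 -0.89 ± 0.16, Thbs1 -0.69 ± 0.21, Cyp51 -0.50 ± 0.10, Rps27l -0.35 ± 0.11, H2bc7 -0.43 ± 0.13, Cul3 -0.41 ± 0.12 and Synpo2 -0.46 ± 0.15. At the high against the low dose the rises were Klf6 0.89 ± 0.25, Stat2 0.48 ± 0.17, Irf1 0.41 ± 0.12, Bbc3 0.61 ± 0.12, Egln3 0.93 ± 0.25, Ndrg1 0.59 ± 0.18, Pgam2 0.41 ± 0.14, Bcl6 0.87 ± 0.26, Stard4 0.60 ± 0.20, Rcan1 0.63 ± 0.18, Mcl1 0.38 ± 0.10, Des 0.40 ± 0.13 and Flt1 0.90 ± 0.29. The falls there were Mafk -0.68 ± 0.17, Jun -0.58 ± 0.18, Sqstm1 -0.58 ± 0.11, Cat -0.56 ± 0.15, Vcam1 -0.94 ± 0.24, Tnfaip3 -0.67 ± 0.14, Gbp2 -0.67 ± 0.16, Tnfrsf10b -1.12 ± 0.25, Pmaip1 -0.62 ± 0.15, Egln1 -0.90 ± 0.15, Hk1 -0.94 ± 0.21, Pfkp -0.84 ± 0.13, Sdhb -0.59 ± 0.13, Hes1 -0.65 ± 0.13, Myl9 -0.61 ± 0.17, Cyp51 -0.76 ± 0.11, Sqle -0.70 ± 0.14, Rpl30 -0.60 ± 0.19, Rpl18 -0.45 ± 0.13, Casq1 -0.81 ± 0.25, Bcl2l1 -1.10 ± 0.20, Nppb -0.58 ± 0.18, Actg2 -0.58 ± 0.16, Pcp4l1 -0.46 ± 0.14 and Fn1 -1.0 ± 0.21. Of the genes reported whatever their values, none of these passed between the doses: Fos 0.77 ± 0.38, Egr1 0.35 ± 0.20, Atf3 -0.32 ± 0.22, Dusp1 0.14 ± 0.13, Myc -0.05 ± 0.19, Hmox1 -0.32 ± 0.13, Hspa1a -0.84 ± 0.50, Hspa1b -0.67 ± 0.34, Cdkn1a 0.07 ± 0.12, Myog 0.07 ± 0.16, Acta1 0.08 ± 0.30 and Gapdh -0.10 ± 0.11. Without high dose array 3, Egr1 passed at 0.64 (adjusted p = 0.0107), while Atf3 lay at 0.00, Hspa1a at 0.13, Hspa1b at -0.09, Acta1 at -0.45 and Cdkn1a at -0.01. Without that array these calls between the doses were lost: Jun (-0.34), Stat2 (0.38), Egln3 (0.61), Ndrg1 (0.33), Pgam2 (0.29), Bcl6 (0.39), Myl9 (-0.37), Stard4 (0.52), Rpl30 (-0.30), Rcan1 (0.35), Casq1 (-0.47), Des (0.23), Nppb (-0.28) and Pcp4l1 (-0.27), besides Calr and Ddit3, and Vcam1 lay at -0.59. At the high dose against vehicle those of Dusp7 (0.25), Hif3a (0.38), Egln3 (0.38), Slc2a1 (-0.22), Sdhc (0.20), Acta2 (0.21) and Egfl7 (0.20) were lost, and Nppb lay at -0.43. Many of these calls are near the threshold or depend on the scaling between arrays, as the values under the alternatives show.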
